A study of Caenorhabditis elegans with 6 samples.

How the data were processed

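The 6 DamID libraries from embryos of C. elegans comprise 3 carrying Dam::EMR-1 and 3 carrying GFP::Dam, grouped and numbered by their titles. The titles name a different strain for each group, so strain and construct cannot be told apart. Per the labels' protocols, worms were grown at 20 °C on bacteria without Dam methylation, 4000 adults per strain were bleached after 72 h, and DamID was run on 200 ng of genomic DNA with 24 PCR cycles before library preparation and sequencing. The labels give EMS as the cell type of every library.

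The deposited tables cover GATC sites and bins of 2, 10 and 100 kb on chromosomes I to V and X, with 173752, 45403, 9960 and 1004 entries. The genome build ce11 and the tool DESeq2 are named in the submitters' processing notes, without a role or version for the tool. The aligner, the treatment of reads that map to several places and the step that made the ratios are not given in the sources used here. Each table holds, per the file headers, a deposited log2 ratio for each of 3 replicate numbers, a deposited count of raw reads summed over the libraries, the authors' average log2 value and the authors' adjusted p-value. From the values, each deposited log2 ratio is log2 of (reads + 1) in Dam::EMR-1 over (reads + 1) in GFP::Dam for libraries of the same number, minus a constant that sets the column's mean over all bins to 0. The header does not say which group is the numerator, and Dam::EMR-1 was taken as the numerator from the naming of the tables and the usual form of a DamID ratio. No entry has fewer than 10 reads in all. The number of per-sample columns left unused was 0.

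Whole reads per library were recovered from each ratio and read sum, with a tolerance of 4e-12 on the log2 scale. This gave a unique solution for 90.2% of GATC sites, 90.1% of 2-kb, 96.3% of 10-kb and 99.9% of 100-kb bins, and 0 entries without a solution. In simulated tables all unique solutions were right, and 60.7% of GATC entries had no solution once the sums were shuffled. Depth per library was taken from the 100-kb table. The median number of reads per entry over the 6 libraries was 164 for GATC sites, 819 for 2-kb, 6256 for 10-kb and 89912 for 100-kb bins. PCR duplicates cannot be told from independent molecules, so read counts understate the counting error.

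The planned test for counts was edgeR, but the tables hold ratios, so the form planned for ratios became the main test: limma with an intercept only on the 3 log2 ratios, with a variance trend on log2 of the read sum, robust estimation and Benjamini-Hochberg adjustment at 0.05, two-sided. Entries with fewer than 60 reads over the libraries were left out. The authors' centring was kept. Domains were runs of at least 2 neighbouring 10-kb bins called in the same direction. Each chromosome was divided into 3 segments of equal length, and the outer and middle segments, and X and autosomes, were compared per replicate ratio and, on recovered reads, per library as log2(CPM + 1), with exact two-sided permutation tests of 3 against 3 libraries. Reads summed over the 18 segments were tested with edgeR's quasi-likelihood test.

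Gene coordinates came from a RefSeq gene table of WBcel235, whose chromosome lengths match ce11. A gene's ratio was the mean over GATC sites in its body and 500 bp on each side. Of 19293 protein-coding genes with a listed site, 18648 passed the read minimum, with a median of 6 sites. The 12 hand-picked lists and 18 families or classes were fixed before the data were examined. They comprise zygotic and maternal EMS regulators, markers of intestine, pharynx, body wall muscle, epidermis, neurons and germline, housekeeping, Hox and heat shock genes, and factors of the nuclear periphery; and chemoreceptors, nuclear hormone receptors, C-type lectins, F-box, MATH-domain, collagen, histone, cytosolic ribosomal protein, major sperm protein, UGT, cytochrome P450, GST, homeobox, neuropeptide and nuclear pore genes, tRNA genes, piRNA genes and pseudogenes. Each was tested with camera at a preset correlation of 0.01, adjusted over the 30 lists. The rotation test moved list positions around the joined chromosomes 10000 times and compared medians. The segment test drew 10000 lists matched on chromosome segment and compared means.

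Genes named are every measured zygotic EMS regulator, up to 4 members with the smallest adjusted p of each other hand-picked list and up to 2 of each family, the 10 highest and 10 lowest called genes with more reads than the median gene (1932) and all replicates in the same direction, the 5 longest domains per direction, emr-1 and med-1.

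Alternatives were no read minimum, total-read scaling, an adjusted p of 0.01, pseudocounts of 0.1 and 5, gene bodies alone, removal of the trend on GATC site number, fits with and without the replicate number as a block, and each replicate or library left out. Pseudocounts were changed on recovered reads. Because the ratios take libraries of the same number together, the fit without a block used recovered reads. Fits on recovered reads with edgeR and DESeq2, and centring on the median, were added after the data were seen. The alternatives on GC content and on 1 kb around gene starts were not run, because no genome sequence or strand was used here.

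The tests were run on simulated data drawn from the spread of the real replicates. With 200 entries changed, limma called 1.47%, 7.58% and 84.8% of 10-kb bins changed by 2, 4 and 8 on the log2 scale, and 1.47%, 45.5% and 100% of such genes, with 1 and 5 false calls. At 2 kb it called 0% at each of these sizes, and at 100 kb 100%, with 8.26% of calls false, above the nominal 5%. With a share of 0.5 of the entries changed, as is closer to the calls made here, it called 35.6%, 88.4% and 99.3% of changed 10-kb bins, 44.3%, 95.1% and 100% of changed genes and 5.82%, 44.7% and 93.3% of changed 2-kb bins, with 2.08%, 2.80% and 2.49% of calls false. These sizes, and the simulation with many changes, were set after a first run at smaller sizes had called almost none of the 200 entries. In the simulation with 200 changed entries, edgeR called 5.88%, 78.8% and 97.0% of changed 10-kb bins and 0%, 7.69% and 79.7% of changed genes at these sizes, with 4.0% and 1.75% of calls false, so a gene that did not pass in edgeR can still be changed. DESeq2 on simulated reads gave 32.3% false calls for 10-kb bins and 57.5% for genes. On simulated lists of 20 random genes, camera called 100% of lists shifted by 3 and 2.78% of others. Rotation called 95.0% of lists shifted by 4 and 7.5% of others, and the segment test 100% and 0%. The 7.5% is above the nominal 5%, but with 60 lists, 20 of them shifted, it cannot be told from it. The genes of the camera run held no other difference, and random genes are not clustered as many families are. These false rates may therefore not hold for the real lists.

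Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.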

Results

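DNA adenine methyltransferase identification (DamID) was used to ask which chromatin lies at the nuclear periphery in the EMS lineage of early Caenorhabditis elegans embryos. EMS is a founder blastomere whose descendants form the intestine and parts of the pharynx and body wall muscle. In this assay a bacterial methyltransferase, Dam, marks GATC sequences near the protein it is fused to, and the marked fragments are amplified and sequenced. The 6 libraries fell into 2 groups of 3: Dam fused to EMR-1, the worm emerin, a protein of the inner nuclear membrane, and GFP::Dam, which is not tethered there and records how accessible chromatin is to a diffusing methyltransferase. The deposited tables hold 1 log2 ratio per replicate number for each of 173752 GATC sites and for bins of 2, 10 and 100 kb. All ratios are given here as Dam::EMR-1 over GFP::Dam. The tables themselves do not state which group is on top, so every direction below, and the group to which each recovered depth, read level and read share is assigned, rests on their naming after EMR-1 and on the usual form of a DamID ratio. With the opposite order all signs would turn and these values would swap groups. "Enriched" means a higher and "depleted" a lower level in Dam::EMR-1.

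Reads recovered from the 100-kb table came to 22407988, 15719682 and 17358287 in Dam::EMR-1 replicates 1 to 3 and to 17535839, 16278015 and 17474703 in GFP::Dam. Between replicates, ratios correlated across bins at r of 0.945 to 0.953 for 100 kb, 0.786 to 0.799 for 10 kb and 0.673 to 0.692 for 2 kb, bins not being independent replicates. Over GATC sites, log read levels correlated at 0.698 to 0.731 among Dam::EMR-1 libraries, at 0.857 to 0.876 among GFP::Dam libraries and at -0.03 to 0.07 between the groups. GFP::Dam reads were more concentrated, with 43.1% to 46.0% of them on the 1% of sites with the most reads, against 23.7% to 24.5% in Dam::EMR-1. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, possibly technical.

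The first comparison asked where along each chromosome EMR-1 contacts lie. On each of the 5 autosomes the outer segments were higher than the middle segment, each chromosome being divided into 3 segments of equal length. The mean log2 ratio of 10-kb bins was higher in the outer segments by 2.41 ± 0.31 on chromosome III, 2.02 ± 0.33 on I, 1.99 ± 0.50 on II, 1.87 ± 0.30 on IV and 1.86 ± 0.29 on V (SD, n = 3). On X the difference was 0.68 ± 0.13 (SD, n = 3). On all 6 chromosomes the difference was above 0 in 3 of 3 replicates. The highest single segment was the right end of V, where the mean ratio was 1.77 ± 0.14 and 48.4% of 10-kb bins were enriched and 10.8% depleted. The lowest by mean ratio was the middle of III, with -2.25 ± 0.18, 12.5% of bins enriched and 47.6% depleted (SD, n = 3).

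Read levels of each library showed which group carried this difference. In GFP::Dam the outer segments of autosomes lay below the middle, by between -1.26 ± 0.05 on V and -1.42 ± 0.07 on III on the scale of log2(CPM + 1), CPM being reads scaled to the library total. In Dam::EMR-1 they lay above it, by between 0.24 ± 0.19 on IV and 0.72 ± 0.20 on III (SD, n = 3). On every chromosome each of the 3 Dam::EMR-1 libraries was above each of the 3 GFP::Dam libraries. The exact two-sided permutation test gave p = 0.1 on every chromosome, the smallest value that 3 against 3 libraries allow, so the design could not reach 0.05 by this test. With reads summed per segment, the level differed between the groups in all 18 segments by edgeR's quasi-likelihood test, which pools the spread over segments, and the smallest difference was in the right segment of II (log2 change 0.12, adjusted p = 0.017). On these summed reads the order of segments differed: the lowest were the middle segments of X (-1.23), I (-1.11) and II (-1.06), while the middle of III had -0.28, close to -0.23 in the right segment of III and below 1.04 in the left one. The middle of III contains an interval of 10 kb at plg-1, with 2.67% of Dam::EMR-1 and 0.016% of GFP::Dam reads, and the order was not computed without it.

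**Figure D1:**
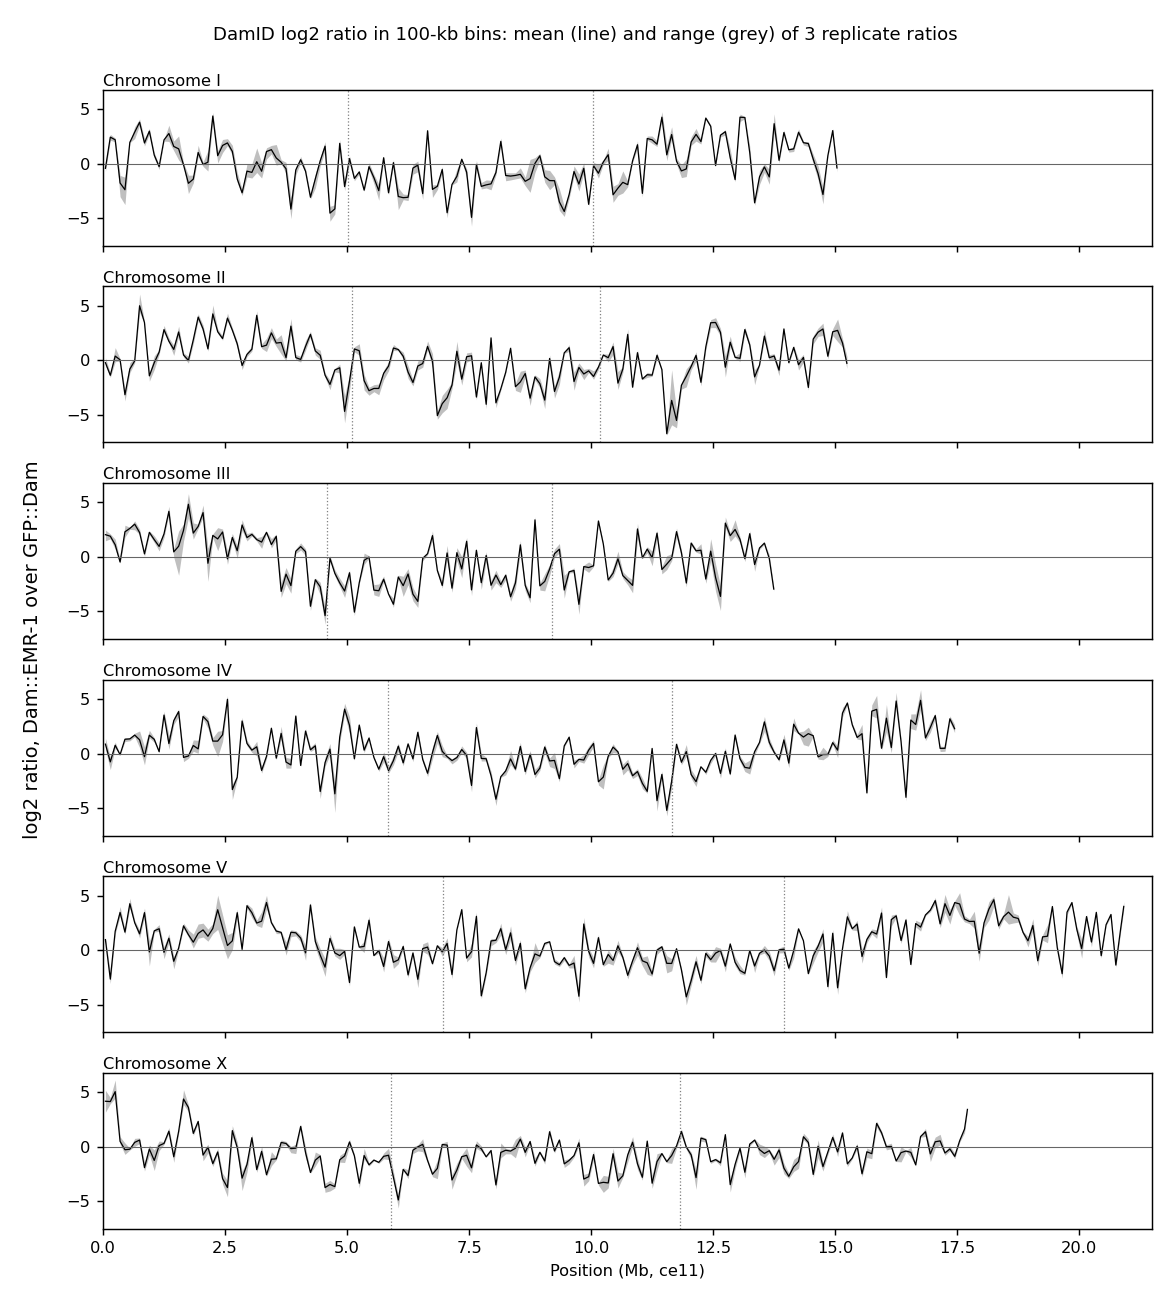
Log2 ratio of Dam::EMR-1 over GFP::Dam (vertical axis) along the 6 chromosomes in Mb of ce11 (horizontal axis) in 100-kb bins, with the line giving the mean and the grey band the range of 3 replicate ratios, and dotted lines dividing each chromosome into 3 equal segments. Outer segments of the 5 autosomes lie above the middle ones, by 1.86 to 2.41 in 10-kb bins.

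**Figure D2:**
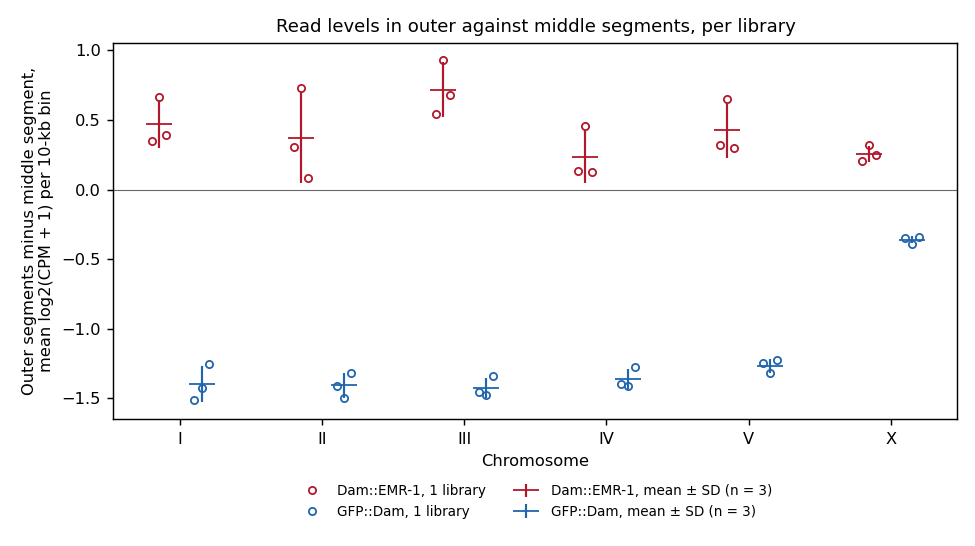
Mean log2(CPM + 1) of 10-kb bins in the outer segments minus that in the middle segment (vertical axis) for each chromosome, with an open circle per library and the mean with SD of 3 libraries per group. Dam::EMR-1 libraries lie above 0 and GFP::Dam libraries below 0 on all 6 chromosomes.

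The X chromosome had a lower share of reads in Dam::EMR-1. It held 13.9% ± 0.256 of Dam::EMR-1 reads and 22.01% ± 0.386 of GFP::Dam reads (SD, n = 3), while making up 17.7% of the genome. The exact two-sided permutation test again gave its smallest value, p = 0.1. The mean ratio of 10-kb bins differed between X and the autosomes together by -0.56 ± 0.18 (SD, n = 3), but X itself, at -0.45 ± 0.15, lay between III and I. Its tips stood apart from the rest of X: the mean ratio was 1.17 ± 0.05 in the first Mb, 1.44 ± 0.25 in the Mb after it and 0.88 ± 0.16 in the last one, and at most 0.05 ± 0.35 in each of the others (SD, n = 3). Chromosome V had the highest mean ratio, 0.81 ± 0.11, with 22.3% ± 0.185 of Dam::EMR-1 and 16.6% ± 0.136 of GFP::Dam reads. Chromosome IV followed with 0.47 ± 0.11. The signs of I, II (-0.10 ± 0.04) and X rest on the authors' centring, since scaling by total reads would raise all 10-kb ratios by 0.60 on average. That of III is not secure either, as the shift ran from 0.41 to 0.88 between replicates. On I and III the mean ratio was below 0, at -0.40 ± 0.11 and -0.65 ± 0.16, although both held a larger share of reads in Dam::EMR-1 than in GFP::Dam (16.3% ± 0.224 against 15.3% ± 0.0556, and 15.5% ± 0.143 against 14.6% ± 0.126; SD, n = 3). On III this excess is smaller than that of the plg-1 interval alone, so the rest of III held a smaller share in Dam::EMR-1.

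Enriched and depleted bins formed domains across the genome. Of 9914 bins of 10 kb, 2812 were enriched and 2502 depleted in limma at an adjusted p of 0.05. Runs of neighbouring called bins gave 573 enriched domains with a median of 30 kb, covering 22.4 Mb or 22.3% of the genome, and 576 depleted domains with a median of 20 kb, covering 17.9 Mb or 17.8%. Enriched domains covered 6630 kb of chromosome V and 4910 kb of IV but 2019 kb of X. Depleted domains covered 3400 kb of I, 3340 kb of X and 3210 kb of III, which make up 15.0%, 17.7% and 13.7% of the genome. Called from 2-kb bins instead, domains numbered 1608 enriched and 1636 depleted, covered 11.6 and 10.4 Mb and had medians of 6 and 4 kb. A domain holds at least 2 bins, so 20 kb is the shortest length that full 10-kb bins allow. The medians thus depend on bin width and do not give the size of domains.

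The longest enriched domains lay in the outer segments of chromosome V and on IV. The longest spanned V 3230001 to 3430000, with a mean ratio of 4.25 ± 0.44 and 62 protein-coding genes, 16 of them chemoreceptor genes. The next ones were V 17130001 to 17310000 (4.53 ± 0.40, 35 genes, 20 of them chemoreceptor genes), V 18140001 to 18320000 (4.73 ± 0.58, 39 genes, 5 of them C-type lectins), V 17370001 to 17540000 (4.95 ± 0.91, 33 genes, 17 of them chemoreceptor genes) and IV 2440001 to 2600000 (4.89 ± 0.71, 22 genes). The longest depleted domains were III 5830001 to 6030000 (-5.48 ± 0.62, 51 genes), III 4460001 to 4600000 (-6.12 ± 1.19, 30 genes), I 3780001 to 3910000 (-4.60 ± 0.97, 37 genes), II 11530001 to 11640000 (-6.96 ± 0.15, 25 genes) and III 5160001 to 5260000 (-6.02 ± 0.81, 28 genes). All values are means with SD of 3 replicates, and none of the 5 depleted domains held a chemoreceptor gene.

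At the other resolutions limma called 370 enriched and 382 depleted of 1004 bins of 100 kb, and 7879 enriched and 7056 depleted of 41117 bins of 2 kb. Scaling by total reads in place of the authors' centring raised 10-kb ratios by 0.60 on average (between 0.41 and 0.88 in the 3 replicates) and gave 3429 enriched and 2012 depleted bins, so that the enriched share of calls rose from 52.9% to 63.0%. At 2 kb that share rose from 52.8% to 62.5%, and leaving out any single replicate reduced calls to between 2174 and 2774 enriched and between 3163 and 3666 depleted.

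Gene ratios were the mean over GATC sites in each gene and 500 bp on either side. Of 18648 protein-coding genes tested by limma, 5639 (30.2%) were enriched and 5064 (27.2%) depleted at an adjusted p of 0.05, and the median gene had a ratio of 0.31. Counting summed reads with edgeR's quasi-likelihood test gave 3299 enriched and 3132 depleted genes. Scaling by total reads raised each gene's ratio by 0.26 on average. The 30 gene lists were fixed before the data were examined and tested with limma's camera against the other genes, at a preset correlation between genes. With an estimated correlation camera also uses the residual degrees of freedom of the fit, which are few with these replicate ratios. Adjusted p-values with an estimate can therefore miss 0.05 whatever the correlation between genes. Where no other count is given, adjusting over the list alone called as many members in each direction.

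Regulators of the EMS lineage were low or not called. In the list of 11 zygotic regulators 6 were depleted and none enriched, with a median ratio of -3.06 (camera, adjusted p = 0.035; adjusted p = 0.24. with an estimated correlation) Of the endoderm GATA factors end-3 was not called and 3 were depleted: end-1, which specifies endoderm, had a ratio of -5.88 ± 1.01 (limma, adjusted p = 6.5e-05), elt-2, the main transcription factor of the intestine, -3.33 ± 1.09 (adjusted p = 0.0029) and elt-7 -3.06 ± 1.49 (adjusted p = 0.02; SD, n = 3). The pharynx selector pha-4 (-3.85 ± 1.04, adjusted p = 0.00057), the mesoderm homeobox gene ceh-51 (-3.13 ± 1.67, adjusted p = 0.013) and sdz-26 (-3.17 ± 2.16, adjusted p = 0.012) were also depleted in limma (SD, n = 3). On summed reads by edgeR's quasi-likelihood test, pha-4 was smaller and did not pass (log2 change -1.54, adjusted p = 0.13), while elt-7 (-3.50, adjusted p = 0.075) and sdz-26 (-3.88, adjusted p = 0.063) kept their size but did not pass. With total-read scaling in edgeR, ceh-51 (adjusted p = 0.12) and elt-2 (adjusted p = 0.093) did not pass either. Leaving out 1 replicate in limma ended the calls of sdz-26 (adjusted p = 0.088 without replicate 1 and 0.055 without replicate 2), elt-7 (0.10 without replicate 1 and 0.077 without replicate 3) and ceh-51 (0.092 without replicate 1). Ratios that did not pass were 1.21 ± 0.52 for med-1 and 1.05 ± 2.49 for med-2, the GATA factors at the top of the endomesoderm cascade (SD, n = 3). med-1 rests on 1 site, and reads of a construct with its promoter cannot be separated from its value. med-2 rests on 2 sites and 108 reads over all libraries, with replicate ratios of -1.09, 0.46 and 3.78. The other ratios that did not pass were -0.12 ± 0.56 for the T-box gene tbx-35, -1.03 ± 2.73 for end-3 and -2.09 ± 1.85 for sdz-1 (SD, n = 3).

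Maternal factors that act on EMS were depleted throughout their list, 11 of 11, with a median of -3.88 (camera, adjusted p = 9e-05; adjusted p = 0.14. with an estimated correlation) skn-1, the maternal activator of the EMS fate, had a ratio of -4.80 ± 0.24, the caudal homologue pal-1 -5.63 ± 0.27, and the Wnt pathway kinase lit-1 -3.88 ± 0.10 (limma, adjusted p = 1.3e-05, 4.3e-05 and 1.3e-05; SD, n = 3). The beta-catenin wrm-1 had -4.09 ± 0.79 (limma, adjusted p = 0.00035; SD, n = 3), but did not pass on summed reads by edgeR's quasi-likelihood test (log2 change -2.49, adjusted p = 0.24).

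**Figure D3:**
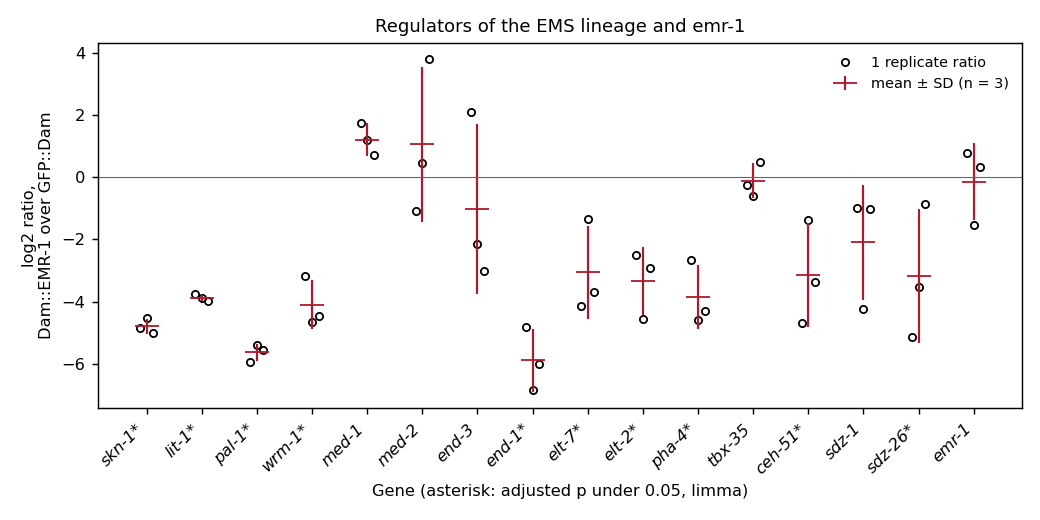
Log2 ratio of Dam::EMR-1 over GFP::Dam (vertical axis) at 4 maternal factors, the 11 zygotic regulators of the EMS lineage and emr-1 (horizontal axis), with an open circle per replicate and the mean with SD of 3. The 4 maternal factors lie between -5.63 and -3.88, while the means of med-1 and med-2 lie above 0 and did not pass the test. Replicate 1 of med-2 lies at -1.09.

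Marker genes of differentiated tissues showed no common direction. Among 19 measured intestine markers 4 were enriched and 6 depleted, with a median of 0.29 against a mean of -0.35. The protease gene cpr-6 had -5.42 ± 0.28 and the GATA factor elt-4 -5.98 ± 1.49, while ifc-2, an intermediate filament gene, had 2.75 ± 0.39 (SD, n = 3). Of 15 pharynx markers 3 were enriched and 4 depleted, and the median of -0.08 turned to 0.18 with scaling by total reads. The depleted ones included the transcription factors peb-1 (-4.63 ± 0.65), ceh-34 (-4.41 ± 0.17) and tbx-2 (-4.56 ± 0.25; SD, n = 3). Of 20 body wall muscle markers 4 were enriched and 11 depleted (median -1.99). The immunoglobulin-domain gene dim-1 had -4.60 ± 0.82 and the integrin pat-3 -4.57 ± 0.71, against 3.04 ± 1.06 for the myosin heavy chain unc-54 and 2.89 ± 0.58 for the M-line gene unc-89 (SD, n = 3). The value of unc-89 fell to 0.22 on summed reads, where edgeR's quasi-likelihood test made no call (adjusted p = 0.68). The camera adjusted p was 0.72 for intestine, 0.64 for pharynx and 0.15 for muscle.

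Markers of lineages outside EMS were measured in the same way. Of 16 epidermis markers 5 were depleted, 4 of them adjusted over the list alone, and none was enriched (median -0.87; camera, adjusted p = 0.31). They included the cuticle collagen bli-2 (-6.73 ± 0.81) and the transcription factors nhr-25 (-4.28 ± 0.77), elt-3 (-3.35 ± 0.19) and nhr-23 (-3.06 ± 0.44; SD, n = 3), the last of which did not pass in edgeR with total-read scaling (log2 change -2.07, adjusted p = 0.076). Of 29 neuron markers 10 were enriched and 5 depleted (median 1.34; camera, adjusted p = 0.47). The vesicular GABA transporter unc-47 had 5.03 ± 0.67, and cha-1 and unc-17, the overlapping genes for acetylcholine synthesis and loading, had 4.88 ± 0.95 and 4.48 ± 1.00, while the homeobox gene ceh-10 had -4.95 ± 1.60 (SD, n = 3). Germline genes were depleted in 12 of 25 cases and enriched in 1 (median -1.33; camera, adjusted p = 0.0083; adjusted p = 0.18 with an estimated correlation and 0.20 with list positions rotated along the genome), and the median relative to their own segments was -1.04. Examples are the egg coat gene cbd-1 (-4.09 ± 0.34), the RNA-binding proteins puf-5 (-5.09 ± 1.59) and oma-1 (-4.16 ± 0.25) and the Notch receptor glp-1 (-3.96 ± 0.34; SD, n = 3). oma-1 did not pass in edgeR with total-read scaling (log2 change -4.05, adjusted p = 0.064). Of the 6 Hox genes ceh-13 was depleted (-2.93 ± 0.75) and egl-5 enriched (3.07 ± 1.08; SD, n = 3), with a median of -0.17 that turned to 0.09 with scaling by total reads (camera, adjusted p = 0.75). Without replicate 3 neither ceh-13 (limma, adjusted p = 0.059) nor egl-5 (0.077) passed. Of 7 heat shock genes hsp-12.3 (-4.39 ± 0.69) and hsp-4 (-3.02 ± 0.13; SD, n = 3) were depleted and 5 did not pass (median -1.85; camera, adjusted p = 0.18). On summed reads hsp-4 did not pass edgeR's quasi-likelihood test (log2 change -1.85, adjusted p = 0.53).

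Lists of genes that are active in nearly all cells had low ratios. All 15 housekeeping genes were depleted, with a median of -3.57 (camera, adjusted p = 1.1e-05; adjusted p = 0.14. with an estimated correlation) The actins act-2 and act-1 had -7.31 ± 0.47 and -5.42 ± 1.58, the tubulin tba-2 -5.46 ± 0.45 and the elongation factor eef-1A.1 -4.86 ± 0.01 (SD, n = 3). Because actin genes are near-identical copies, reads of act-1 and act-2 cannot be assigned with certainty. On summed reads act-1 kept its size but did not pass edgeR's quasi-likelihood test (log2 change -5.32, adjusted p = 0.075). Of 76 cytosolic ribosomal protein genes 68 were depleted, 70 adjusted over the list alone, and 1 was enriched (median -4.74; camera, adjusted p = 5.9e-18; adjusted p = 0.14. with an estimated correlation) rpl-27 had -8.44 ± 0.14 and rpl-31 -7.76 ± 0.93 (SD, n = 3). Histone genes had the lowest median of the 30 lists, -5.32, with 31 of 36 depleted and 1 enriched, or 2 adjusted over the list alone (camera, adjusted p = 6.6e-11; adjusted p = 0.14 with an estimated correlation). his-67 had -10.29 ± 0.70 and his-4 -7.51 ± 0.37 (SD, n = 3), and since histone genes occur as near-identical copies, reads of single members are uncertain. Neighbours such as his-3 and his-4 also share the GATC sites between them, so the count of members overstates the number of independent measurements.

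Among genes for parts of the nuclear envelope, many were depleted and none was enriched. Of 26 nuclear pore genes 17 were depleted and none enriched (median -3.16; camera, adjusted p = 3.2e-05; adjusted p = 0.18. with an estimated correlation) Relative to their own segments the median was -1.996. npp-16 had -6.54 ± 0.91 and npp-2 -6.57 ± 0.46 (SD, n = 3). In the list of 13 factors of the nuclear periphery 10 were depleted and none enriched (median -3.30; camera, adjusted p = 0.00053; adjusted p = 0.21. with an estimated correlation) They included zyg-12, which ties centrosomes to the nucleus (-4.88 ± 1.13), baf-1, which links chromatin to lamina proteins (-5.42 ± 1.35), cec-4, the perinuclear chromodomain anchor (-4.75 ± 0.75), and npp-7 (-5.38 ± 1.02; SD, n = 3). On summed reads npp-7 kept its size but did not pass edgeR's quasi-likelihood test (log2 change -4.96, adjusted p = 0.078). emr-1, which the fusion construct also carries in some form, had -0.15 ± 1.23 (limma, adjusted p = 0.88; SD, n = 3), a value that turned to 0.12 with scaling by total reads and from which reads of a transgene cannot be separated.

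In several large environmental and sensory gene families more members were enriched than depleted. Of 1207 chemoreceptor genes 821 were enriched and 23 depleted, 842 and 24 adjusted over the list alone (median 3.09; camera, adjusted p = 3.1e-19; adjusted p = 0.14. with an estimated correlation) str-256 had 7.37 ± 0.80 and sra-22 7.03 ± 1.11 (SD, n = 3). Of 231 C-type lectins, a family that includes infection-response genes, 161 were enriched and 16 depleted, 162 and 16 adjusted over the list alone (median 3.10; camera, adjusted p = 7.6e-11; adjusted p = 0.14 with an estimated correlation). clec-190 had 7.01 ± 0.35 and clec-167 6.08 ± 1.202 (SD, n = 3). Of 70 MATH-domain genes 47 were enriched and 8 depleted, 48 and 8 adjusted over the list alone (median 3.17; camera, adjusted p = 1.6e-06; adjusted p = 0.14 with an estimated correlation and 0.057 by rotation). bath-47 had 5.999 ± 0.70 and bath-21 5.39 ± 0.75 (SD, n = 3). Of 131 neuropeptide genes 57 were enriched and 10 depleted, 55 and 10 adjusted over the list alone (median 1.90; camera, adjusted p = 0.00058; adjusted p = 0.26 with an estimated correlation). nlp-6 had 6.55 ± 0.65, and nlp-31, a member of a cluster of antimicrobial peptide genes, had -6.25 ± 0.22 (SD, n = 3). Relative to the medians of their own segments, medians were 1.57 for chemoreceptors, 1.80 for C-type lectins and 1.69 for MATH-domain genes.

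In other families, too, more members were enriched than depleted. Collagens counted 55 enriched and 14 depleted of 143, 54 and 13 adjusted over the list alone (median 1.55; camera, adjusted p = 0.011; adjusted p = 0.14 with an estimated correlation), with 5.53 ± 0.78 at col-102 and 5.02 ± 0.65 at col-122 (SD, n = 3). Nuclear hormone receptors counted 116 enriched and 43 depleted of 266, 117 and 44 adjusted over the list alone (median 1.54; camera, adjusted p = 0.0083; adjusted p = 0.21 with an estimated correlation and 0.11 by rotation), with 7.08 ± 0.36 at nhr-265 and -4.90 ± 0.58 at nhr-66 (SD, n = 3). Cytochrome P450 genes counted 35 enriched and 8 depleted of 72 (median 2.02; camera, adjusted p = 0.021; adjusted p = 0.18 with an estimated correlation and 0.11 by rotation), with 5.70 ± 1.26 at cyp-33C11 and 4.98 ± 0.77 at cyp-13A12 (SD, n = 3). F-box genes counted 127 enriched and 50 depleted of 304 (median 1.55; camera, adjusted p = 0.013; adjusted p = 0.31 with an estimated correlation), with 6.66 ± 0.97 at fbxa-35 and -6.36 ± 1.41 at fbxb-76 (SD, n = 3). Of the F-box genes 97.7% lay in outer segments, and against genes of the same chromosome segment the list did not pass (adjusted p = 0.81). Relative to that of their own segments, the median was 0.04 for nuclear hormone receptors and 0.51 for cytochrome P450 genes. The segment test compares means, which exceeded those of the drawn lists by 0.45 and 0.76, and both lists passed it (adjusted p = 0.022 and 0.038).

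The lists of the remaining families did not pass in camera, though GST and UGT genes did against genes of the same chromosome segment and not by rotation. Glutathione S-transferases counted 15 enriched and 6 depleted of 43 (median 1.61; camera, adjusted p = 0.06; adjusted p = 0.033 by segment, 0.047 with gene bodies alone, 0.38 by rotation and 0.37 with an estimated correlation; median 0.69 relative to their own segments), with 6.06 ± 0.67 at gst-26 and 5.27 ± 0.56 at gst-32 (SD, n = 3). UDP-glucuronosyltransferases counted 8 enriched and 17 depleted of 64, 5 and 15 adjusted over the list alone (median -0.52; camera, adjusted p = 0.20; adjusted p = 0.031 by segment, 0.44 by rotation and 0.49 with an estimated correlation), with -6.60 ± 0.39 at ugt-23 and -5.62 ± 0.51 at ugt-11 (SD, n = 3). Genes of the ceh homeobox series counted 13 enriched and 20 depleted of 61, with a median of 0.04 against a mean of -0.25 (camera, adjusted p = 0.57), and ceh-84 had 4.54 ± 0.82 (SD, n = 3). Major sperm protein genes counted 8 enriched and 3 depleted of 28 (median 0.90; camera, adjusted p = 0.49), with 3.02 ± 0.15 at msp-63 and -5.62 ± 3.64 at msp-78 (SD, n = 3). Reads of these near-identical genes cannot be assigned with certainty. On summed reads both kept their size but did not pass edgeR's quasi-likelihood test (3.34 for msp-63 and -5.68 for msp-78, adjusted p = 0.11 and 0.082).

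Gene classes outside the protein-coding genes were compared with them. Of 8155 piRNA genes, which encode germline small RNAs and lie mainly in clusters on chromosome IV, 4475 were enriched and 591 depleted, 4548 and 595 adjusted over the list alone (median 2.89; camera, adjusted p = 1.3e-11; adjusted p = 0.14 with an estimated correlation). Of 1701 pseudogenes 980 were enriched and 118 depleted, 992 and 120 adjusted over the list alone (median 2.72; camera, adjusted p = 4e-10; adjusted p = 0.14 with an estimated correlation). Of 419 tRNA genes 62 were enriched and 174 depleted (median -1.78; camera, adjusted p = 9e-05; adjusted p = 0.14 with an estimated correlation). Relative to their own segments the medians were 1.66 for piRNA genes and 1.42 for pseudogenes. Neighbouring piRNA genes rest on the same GATC sites, so their count overstates the number of independent measurements.

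**Figure D4:**
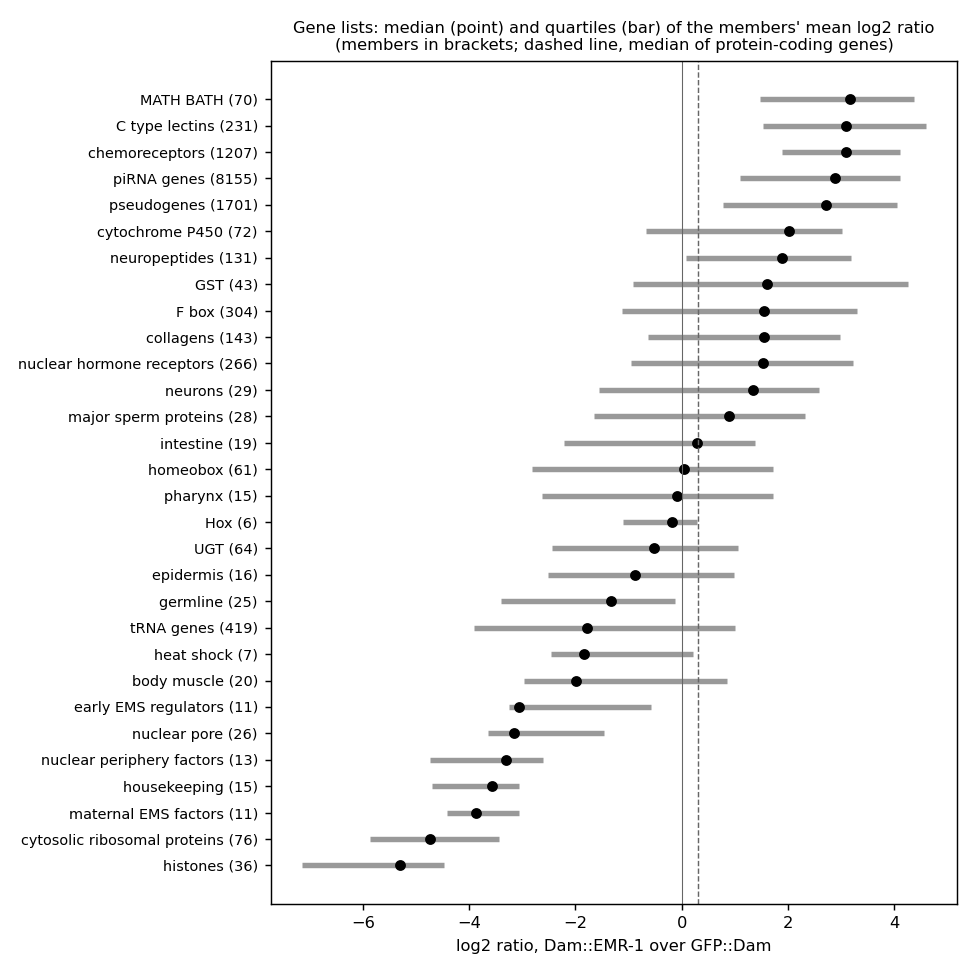
Median (point) and quartiles (bar) of the mean log2 ratio of Dam::EMR-1 over GFP::Dam (horizontal axis) for the members of each of the 30 gene lists (vertical axis, number of measured members in brackets), with a dashed line at 0.31, the median of protein-coding genes. Histone and ribosomal protein genes have the lowest medians, -5.32 and -4.74, and chemoreceptors, C-type lectins and MATH-domain genes the highest, 3.09 to 3.17.

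The 10 genes with the highest ratios among those called, with more reads than the median gene and 3 replicates in the same direction, were scattered over chromosomes I to V. They were led by xbx-4 on IV (2114637 to 2115829), with 8.99 ± 0.74, and nhr-73 on I, with 8.46 ± 1.205 from 1 site (SD, n = 3). The others were F46B3.14, F09C6.15, F46F5.14, Y26D4A.5, T06G6.6, irld-48, Y75B8A.39 and srh-209, between 7.80 and 8.34. The 10 lowest were led by his-67 and by his-3 on V (16040808 to 16041191), with -9.91 ± 1.40, followed by C17H12.2, with -9.86 ± 0.92 from 1 site, and hmg-1.1, a high-mobility-group chromatin protein gene, with -9.76 ± 0.22 (SD, n = 3). The others were R08C7.11, vkmt-1, rab-39, K12H6.2, R11A5.6 and W04D12.1, between -9.52 and -8.84. The adjusted p of these 20 genes in limma lay between 4.5e-06 and 4.7e-05, and few sites underlie each of them, between 1 and 7.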

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

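Fits with edgeR and DESeq2 on recovered reads, centring on the median, the comparison with the authors' adjusted p and the estimated correlation without the replicate number were chosen after seeing the data. The outer-minus-middle difference kept its direction under every other border, bin size, pseudocount and left-out library, between 1.25 and 2.73 on autosomes and between 0.49 and 0.88 on X. X minus autosomes stayed between -0.78 and -0.45. Of 5314 calls at 10 kb, edgeR made 4710 of the 5178 it could test, and 0 in the other direction. The authors' adjusted p passed 0.05 at 3113 bins with a higher and 2914 with a lower ratio.

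A stricter adjusted p of 0.01 left 1541 enriched and 1412 depleted 10-kb bins and 932 and 1723 2-kb bins, as fewer pass a stricter threshold. Pseudocounts were changed on recovered reads, where at 2 kb 0.1 gave 5095 enriched bins, against 7655 with the usual one. At 2 kb edgeR with total-read scaling gave 8345 enriched and 4406 depleted bins. The enriched share of its calls was 65.4%, against 49.4% in edgeR with its own scaling. For genes edgeR gave 3299 enriched and 3132 depleted, and 4434 and 2458 with total-read scaling, so that the enriched share of calls rose from 51.3% to 64.3%. Domains from 2-kb bins numbered 1608 and 1636, over 11.6 and 10.4 Mb. Of the 19 lists called, 0 were left with an estimated correlation and 8 with that and no replicate number. Over these 19 lists the estimate ran from -0.063 for housekeeping genes to 0.081 for factors of the nuclear periphery. It was under the preset 0.01 for ribosomal protein (-0.006) and tRNA genes (-0.001), among others, so a higher correlation did not end those calls. With an estimate camera uses the few residual degrees of freedom of the fit, which it does not with a preset value. The adjusted p-values with an estimate therefore cannot show whether correlation between genes ends a call. Of all 30 lists, 14 passed by rotation and 20 against genes of the same segment. Beyond this, the causes of the changes in this paragraph were not tested.

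Leaving out 1 replicate in limma gave 1850 to 2183 enriched and 1731 to 1961 depleted bins at 10 kb, 2174 to 2774 and 3163 to 3666 at 2 kb, and 4392 to 4765 and 4092 to 4395 genes. Leaving out 1 library in edgeR gave 2233 to 2483 and 1804 to 2305 at 10 kb, 2473 to 4639 and 3597 to 5793 at 2 kb, and 2034 to 2813 and 2090 to 3308 genes, against 5526 and 5671 2-kb bins and 3299 and 3132 genes with all libraries in edgeR. For these the cause was not tested.

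With the replicate number as a block (replicate block), limma on recovered reads gave 2735 enriched and 2456 depleted 10-kb bins. edgeR with this block gave 3191 and 4533 2-kb bins and 2258 and 2703 genes. With the block sdz-1 passed in limma on recovered reads (-2.39, adjusted p = 0.039, and 0.027 with a pseudocount of 0.1) but not in edgeR (adjusted p = 0.27), and in edgeR ceh-51 (adjusted p = 0.099), elt-2 (0.057), egl-5 (0.072), nhr-23 (0.060) and hsp-12.3 (0.074), which passed without it, did not. At 10 kb, libraries of the same number correlated after group means were removed at r of -0.005, 0.004 and 0.00, no better than those of different numbers. For genes these values were -0.048, -0.064 and -0.030. They give no sign that the numbers pair the samples, but cannot show how the samples were prepared. The main limma test on ratios may therefore rest on arbitrary pairs of libraries.

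Among 97 named genes 86 had the same call and direction in edgeR, 10 kept their direction but no longer passed, and 1, emr-1, turned. With a GFP::Dam library left out of edgeR, between 74 and 78 had the same call and between 18 and 22 no longer passed. With a Dam::EMR-1 library left out, between 82 and 86 had the same call. Calls lost in 1 or more of these fits included pat-3, unc-54, unc-47, unc-17 and nhr-25. The Hox list, not called, turned from lower to higher against genes of the same segment (mean difference 1.19, adjusted p = 0.38). The uncalled tbx-35 turned to 0.14 with total-read scaling and 0.018 in edgeR with it, and ranged from -1.08 with a library left out in edgeR to 0.13 with a replicate left out in limma. In limma med-2 ranged from -0.32 to 2.12 with a replicate left out. The value of emr-1 turned to 0.12 with total-read scaling, 0.22 without and with the block, 0.17 and 0.23 with pseudocounts of 0.1 and 5, 0.66 in edgeR, 1.29 with total-read scaling, 1.61 with the block and 0.64 in DESeq2, ranging from -0.62 with a replicate left out in limma to 2.39 with a library left out in edgeR. For these genes the cause was not tested. Read depth was lower in smaller bins: 4286 2-kb bins fell below the read minimum, against 46 of 10 kb and 0 of 100 kb. Corrections for GC content and windows of 1 kb around gene starts were not run, for want of sequence and strand.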

Other observations

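Tests of the read share and of mean log2 reads in each group, of chromosome position and of other splits of the libraries were chosen after the results were seen, as were the intervals and chromosome ends given below, while the tests on GATC density, read depth, read-rich sites and coding density were set before.

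The higher ratios in the outer segments of autosomes might come from uneven GATC density, from bins with few reads or from the GFP::Dam control alone. After removing the trend on GATC site number the mean difference over 5 autosomes was 1.73 ± 0.26, against 2.03 ± 0.34 before (SD, n = 3), so GATC density does not account for it. With the 5821 bins of many reads it was 2.46 ± 0.29 (SD, n = 3), so it was also present in such bins. They were chosen on reads summed over both groups, and a bin can pass through the group that is high there. The test on read depth therefore cannot exclude a part for bins with few reads. In Dam::EMR-1 the outer segments held 74.5% ± 2.02 of autosomal reads and in GFP::Dam 52.6% ± 1.06, while holding 63.0% of GATC sites, so both groups depart from the sites, in opposite directions. By mean log2 reads per bin the Dam::EMR-1 libraries alone gave 0.445 ± 0.211 (0.32 to 0.69, above 0 in 3 of 3) and GFP::Dam -1.37 ± 0.08 (SD, n = 3). By this measure, which unlike the share of reads was not set against GATC sites, GFP::Dam carries the larger part. The Dam::EMR-1 part is only just past the bound of 2 SD, which was itself set after these values were seen.

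The lower share of reads on X in Dam::EMR-1 might come from a few sites with very many reads or from GATC density. Without the 1% of sites with the most reads, X held 14.6% ± 0.340 of reads in Dam::EMR-1 and 22.2% ± 0.381 in GFP::Dam, a difference of -7.68 ± 0.511 points. A few read-rich sites therefore do not account for the lower share. After removing the trend on GATC site number, the mean ratio of X minus autosomes was -0.716 ± 0.197, against -0.559 ± 0.181 before (SD, n = 3). GATC density thus does not account for the lower mean ratio of X, but it was not tested on the share of reads.

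The low ratios at ribosomal protein and histone genes might come from the control alone, since open chromatin is marked more by a diffusing methyltransferase. Relative to protein-coding genes, their median level was -2.89 ± 0.24 in Dam::EMR-1 and 2.88 ± 0.27 in GFP::Dam (SD, n = 3), so both groups contribute about equally. Compared with their own chromosome segments the lists had medians lower by -4.60 and -5.18, so position along the chromosome does not account for them.

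The splits were fitted with limma on recovered reads per library without a block, not with the ratio fit of the report. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls as the real grouping, namely the real one: 5549 bins of 10 kb, 16702 of 2 kb, 758 of 100 kb and 10988 genes, with at most 0 in any other split. Every other split mixes the groups and so adds their difference to the residual spread. So few splits cannot give a share under 0.05.

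A hypothesis was that bins with more coding sequence have lower ratios within every chromosome segment. The rank correlation was below 0 in 17 of 18 segments, from -0.334 in the right segment of IV to 0.011 in the left segment of I, so the prediction for all 18 was not met.

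An interval around plg-1 on III (8852001 to 8862000), 0.01% of the genome, held 2.67% ± 0.142 of Dam::EMR-1 and 0.016% ± 0.002 of GFP::Dam reads, and the ribosomal DNA interval on I (15060001 to 15070000) 1.15% ± 0.341 and 1.27% ± 0.066 (SD, n = 3). In the end bins of the 100-kb table, which are shorter at the right ends, left and right ratios were -0.43 ± 0.47 and -0.40 ± 0.35 on I, -0.22 ± 0.40 and -0.28 ± 0.59 on II, 2.04 ± 0.51 and -2.96 ± 0.18 on III, 0.86 ± 0.52 and 2.28 ± 0.37 on IV, 0.97 ± 0.21 and 4.02 ± 0.39 on V, and 4.19 ± 1.00 and 3.44 ± 0.18 on X (SD, n = 3). The 10-kb bins richest in GFP::Dam reads included that of lit-1 on III, with 0.702% of GFP::Dam and 0.004% of Dam::EMR-1 reads (ratio -8.02 ± 1.05), and that of hsp-3 on X, with 0.589% and 0.001% (-10.35 ± 1.66; SD, n = 3). The right end bin of III contains this lit-1 bin and that of I the ribosomal DNA interval. Ratios of these ends were not computed without them.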
